A study of Aspergillus niger with 16 samples.

How the data were processed

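The arrays were scanned on an Axon scanner and read with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes and the file headers. The deposited scanner files give each spot's mean signal and the median of its local background as intensity in Cy3 and Cy5, per the file headers. Processed signals in the same files are intensity after background subtraction, spatial detrending and dye normalization (linear and lowess), per the file headers. The deposited ratio column is the log10 of Cy5 over Cy3 of these processed signals, per the file headers. The authors' value table of the series holds log2 ratios of Cy5 over Cy3, a scale and direction taken from its quantiles in 16 of 16 columns because no header states them, and how the authors normalized it is not recorded. Its 14107 rows matched no probe, so they stayed unnamed and served for counts alone. Per the labels, 5 µg of RNA was labelled for 2 h at 40 °C, and the fructose RNA of a strain was the Cy3 sample on its own arrays.

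Each array held 44173 spots for 14052 gene probes, with 13992 probes printed 3 times and 60 printed 13 times, and 1417 control spots, which were removed. Of the gene probes 13926 matched a locus tag of the reference gene list (assembly ASM285v2), which gave 127 of them a symbol, and 24 probes shared their sequence with another probe. Each gene had 1 probe. Neither the files nor that list describe gene products, so the functions given for genes are general background. Between 1561 and 1804 spots per array were marked by the software as poor and left out. Median signals lay between 67.4 and 115 in Cy3 and between 52.2 and 80.1 in Cy5.

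Signals were corrected with the normexp model (offset 50) and normalized by loess within each array, spots of a probe were averaged, and M = log2(Cy5/Cy3) was fitted in limma 3.58.1 under R 4.3.3 with 1 mean per group over all 16 arrays. limma's moderated test had 8 residual and 2.41 prior degrees of freedom, was 2-sided, and was adjusted by Benjamini and Hochberg within each comparison at 0.05. Kept were 9173 probes well above background in at least 1 channel on both arrays of at least 1 group, of which 5 lacked a value in some group. For fructose levels, log2 Cy3 signals were also scaled between arrays (Aquantile), and the 2 h and 8 h arrays of a strain and number were averaged first. Software also included statmod 1.5.0, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

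The labels call the arrays biological replicates 1 and 2 of 2 but do not say that they came from separate cultures, so p-values measure the spread between these samples and no more. The number of arrays limits the precision. Replicate numbers coincided with the scan day. The labels do not say that a number pairs samples, so the fits were unpaired. Slides 1 and 3 held WT and ΔXlnR, slides 2 and 4 ΔaraR and ΔaraRΔXlnR. Each group had the same position on both of its slides. Within a slide, position therefore cannot be told apart from strain and time.

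Comparisons, gene lists and the rule for named genes were fixed before the data were examined. By the rule, xlnR and araR were always named. In each WT response, strain difference and the WT time difference the 6 largest rises and 6 largest falls could be named, among called genes that moved alike on both arrays and were well above background in at least 1 channel on every array compared. All measured members of the lists of xylan-degrading enzymes, arabinan-degrading enzymes and pentose catabolism could be named, and from each other list the 4 members with the smallest p. Of 17 lists, 13 had at least 3 measured members and were tested with limma's camera (preset correlation 0.01, and again estimated), the sugar transporters had 2 members, and cytosolic ribosomal proteins, mitochondrial respiration, and heat shock and oxidative stress had none, for want of product descriptions.

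The fits were first tested on simulated data, with 100 genes changed by 1 and 100 by 2 (log2) among 9068 genes. In the WT response at 2 h 77 and 99 of these were recovered with 16 false calls. The difference of ΔXlnR from WT at 2 h recovered 65 and 91 (8 false), the WT time difference 61 and 90 (9 false), and the non-additivity at 2 h 32 and 82 (9 false). The fructose comparison of ΔXlnR recovered 63 and 86 of 100 each (5 false) among 9169 genes. The set test gave a p under 0.05 for 10 of 200 unchanged lists in the simulated WT response at 2 h. Simulated noise was independent between genes and between arrays. These rates therefore do not cover genes or arrays that vary together, as those of the data did.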

Results

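Transcript levels were measured on 16 arrays with 2 dyes in 4 strains of Aspergillus niger: the wild type (WT), strains lacking XlnR (ΔXlnR) or AraR (ΔaraR), and a strain lacking both (ΔaraRΔXlnR). XlnR and AraR are transcription factors of the breakdown of xylan and arabinan and of pentose use. Mycelium was pre-grown for 24 h on fructose at 30 °C and moved to a medium with xylose and arabinose, 25 mM each, for 2 h or 8 h. Every array held the pentose RNA in Cy5 and the fructose RNA of its own strain in Cy3, and each of the 8 groups of strain and time had 2 arrays (n = 2). Between 49.3% and 66.1% of gene probes were well above background in Cy3 and between 51.4% and 63.8% in Cy5, and no more than 10 probes per array were saturated in either channel. No array had the dyes exchanged, so a response within a strain includes any dye effect of a gene, which cancels in the differences between strains. Sizes are log2 ratios of Cy5 over Cy3, or differences of such ratios, with the standard error (SE). The offset added to both channels makes ratios of dim probes smaller than they would be without it. Sizes of dim genes may therefore understate the fold change, and by how much was not tested. Genes were called at an adjusted p under 0.05 of limma's moderated test.

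The deleted genes gave no signal well above background in the strains that lack them. The transcript of xlnR (An15g05810) had Cy5 levels between 7.59 and 7.70 (log2 intensity) in WT and between 7.71 and 8.03 in ΔaraR. In ΔXlnR (5.96 to 6.04) and ΔaraRΔXlnR (6.01 to 6.05) it was well above background on 0 of 4 arrays per strain. The transcript of araR (An04g08600) lay between 6.58 and 6.67 in WT and between 6.51 and 6.64 in ΔXlnR. On 0 of 4 arrays each was it well above background in ΔaraR, where it lay between 5.90 and 6.10, or in ΔaraRΔXlnR. Where a probe was well above background on no array of a group, its fold is given as a bound, computed against the dimmest signal that still counts as above background. By that rule the Cy5 signal of xlnR at 2 h was at least 2.93-fold lower in ΔXlnR and at least 2.83-fold lower in ΔaraRΔXlnR than in WT. The signal of araR was at least 1.42-fold lower in ΔaraR and at least 1.36-fold lower in ΔaraRΔXlnR. After the move to pentoses, xlnR was not called in WT (-0.05 ± 0.09 at 2 h, adjusted p = 0.781). In WT araR was dim, with Cy3 signals between 6.30 and 6.39, so the offset makes its sizes too small. It rose in WT by 0.24 ± 0.07 at 2 h and 0.34 ± 0.07 at 8 h. Without WT 2 h number 1 or 2 its adjusted p was 0.395 or 0.0907, and without WT 8 h number 1 or 2 it was 0.176 or 0.133.

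**Figure D1:**
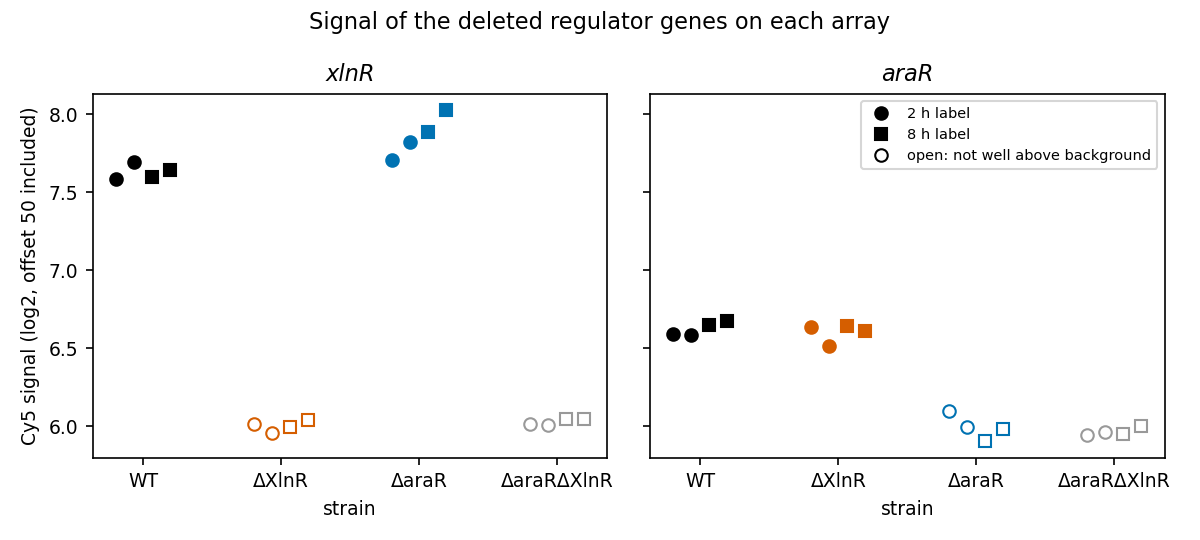
Cy5 signal (log2 intensity, offset 50 included) of xlnR and araR by strain, 1 point per array, open where not well above background. In WT xlnR sat between 7.59 and 7.70 and araR between 6.58 and 6.67, while the strains lacking a gene stayed at 6.10 or under for it.

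The WT response asked which transcripts changed when the fungus met both pentoses. At 2 h the gene xyrA (An01g03740, D-xylose reductase) rose most, by 8.26 ± 0.27 (SE, n = 2 arrays, limma adjusted p = 7.85e-08). The other 3 genes of pentose catabolism rose too, xdhA (An12g00030, xylitol dehydrogenase) by 5.96 ± 0.53, xkiA (An07g03140, xylulose kinase) by 4.78 ± 0.23 and ladA (An01g10920, L-arabitol dehydrogenase) by 3.42 ± 0.30. All 7 measured genes for xylan-degrading enzymes rose as well. They included faeA (An09g00120, feruloyl esterase) with 5.62 ± 0.16 (adjusted p = 3.70e-08), xlnD (An01g09960, β-xylosidase) with 5.30 ± 0.27, aguA (An14g05800, α-glucuronidase) with 5.12 ± 0.40 and xynB (An01g00780, endoxylanase) with 4.98 ± 0.20. The smallest rises were those of axhA (An03g00960) with 2.44 ± 0.15 and xynA (An03g00940) with 2.31 ± 0.13. Of 7 measured genes for arabinan-degrading enzymes 3 rose, the arabinofuranosidase genes abfB (An15g02300, 6.29 ± 0.71), abfC (An08g01710, 5.33 ± 0.43) and abfA (An01g00330, 3.02 ± 0.31), and 4 were not called, of which 1 was lower adjusted over the list alone. Where no other count is given, a list had the same calls adjusted over the list alone. Large rises outside these lists were those of An03g01620 (6.36 ± 0.64) and An03g01050 (5.73 ± 0.50). The steepest falls that held without either array were those of An01g12530 (-4.35 ± 0.46), An14g00960 (-2.98 ± 0.36) and An03g00690 (-2.73 ± 0.25), while An01g06860 was at least 6.01-fold lower on the pentoses.

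Other carbohydrate-active enzymes also rose in WT at 2 h. Of 8 genes for cellulases and other hydrolases 6 rose (7 adjusted over the list alone) and 1 fell. Those that rose included lacA (An01g12150, β-galactosidase) with 3.70 ± 0.31, eglA (An14g02760, endoglucanase) with 3.02 ± 0.35, aglB (An02g11150, α-galactosidase) with 2.50 ± 0.27 and bgl1 (An18g03570, β-glucosidase) with 2.45 ± 0.33. In glycolysis pgiA (An16g05420, glucose-6-phosphate isomerase) rose by 1.57 ± 0.22 and gpdA (An16g01830, glyceraldehyde-3-phosphate dehydrogenase) by 1.49 ± 0.19. Of 10 glycolysis genes 4 rose, 1 fell and 5 were not called. All 3 pentose phosphate pathway genes were called higher, among them gsdA with 0.81 ± 0.18 (adjusted p = 0.146 without WT 2 h number 1 and 0.0614 without number 2). In all, 1976 of 9173 genes were called at 2 h, 829 higher and 1147 lower, and 485 without WT 2 h number 1. On each scan day alone, which is the replicate number, xyrA was at 8.17 and 8.35 and xynB at 4.86 and 5.09.

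At 8 h WT still held the pentose and xylan genes high. The gene xyrA was up by 7.83 ± 0.27 (adjusted p = 9.08e-08), faeA by 5.48 ± 0.16, xdhA by 5.22 ± 0.53, xlnD by 5.09 ± 0.27 and xynB by 4.90 ± 0.20. The acetyl xylan esterase gene aceA (An12g05010) was up by 3.08 ± 0.38, and again 4 of 4 pentose and 7 of 7 xylan genes had risen. The arabinofuranosidase genes abfB (5.70 ± 0.71), abfC (4.38 ± 0.43) and abfA (2.76 ± 0.31) rose, with 4 arabinan genes not called, 1 of them lower adjusted over the list alone. Of the 8 genes for cellulases and other hydrolases 7 rose (1 was lower adjusted over the list alone), among them cbhB (An01g11660, cellobiohydrolase, 1.93 ± 0.17), mndA (An11g06540, β-mannosidase, 1.09 ± 0.15), lacA (3.27 ± 0.31) and aglB (2.45 ± 0.27). The gene glaA (An03g06550, glucoamylase) fell by 1.67 ± 0.16. Larger falls were those of An01g12530 (-5.16 ± 0.46), An07g01320 (-3.67 ± 0.23) and An04g08150 (-2.99 ± 0.21). Calls at 8 h numbered 1345 of 9171 genes (698 higher, 647 lower, but 624 higher and 201 lower with arrays scaled by their medians), 242 without WT 8 h number 1 and 447 without number 2. On scan days 1 and 2 xyrA was at 7.55 and 8.12 and xynB at 4.91 and 4.89.

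**Figure D2:**
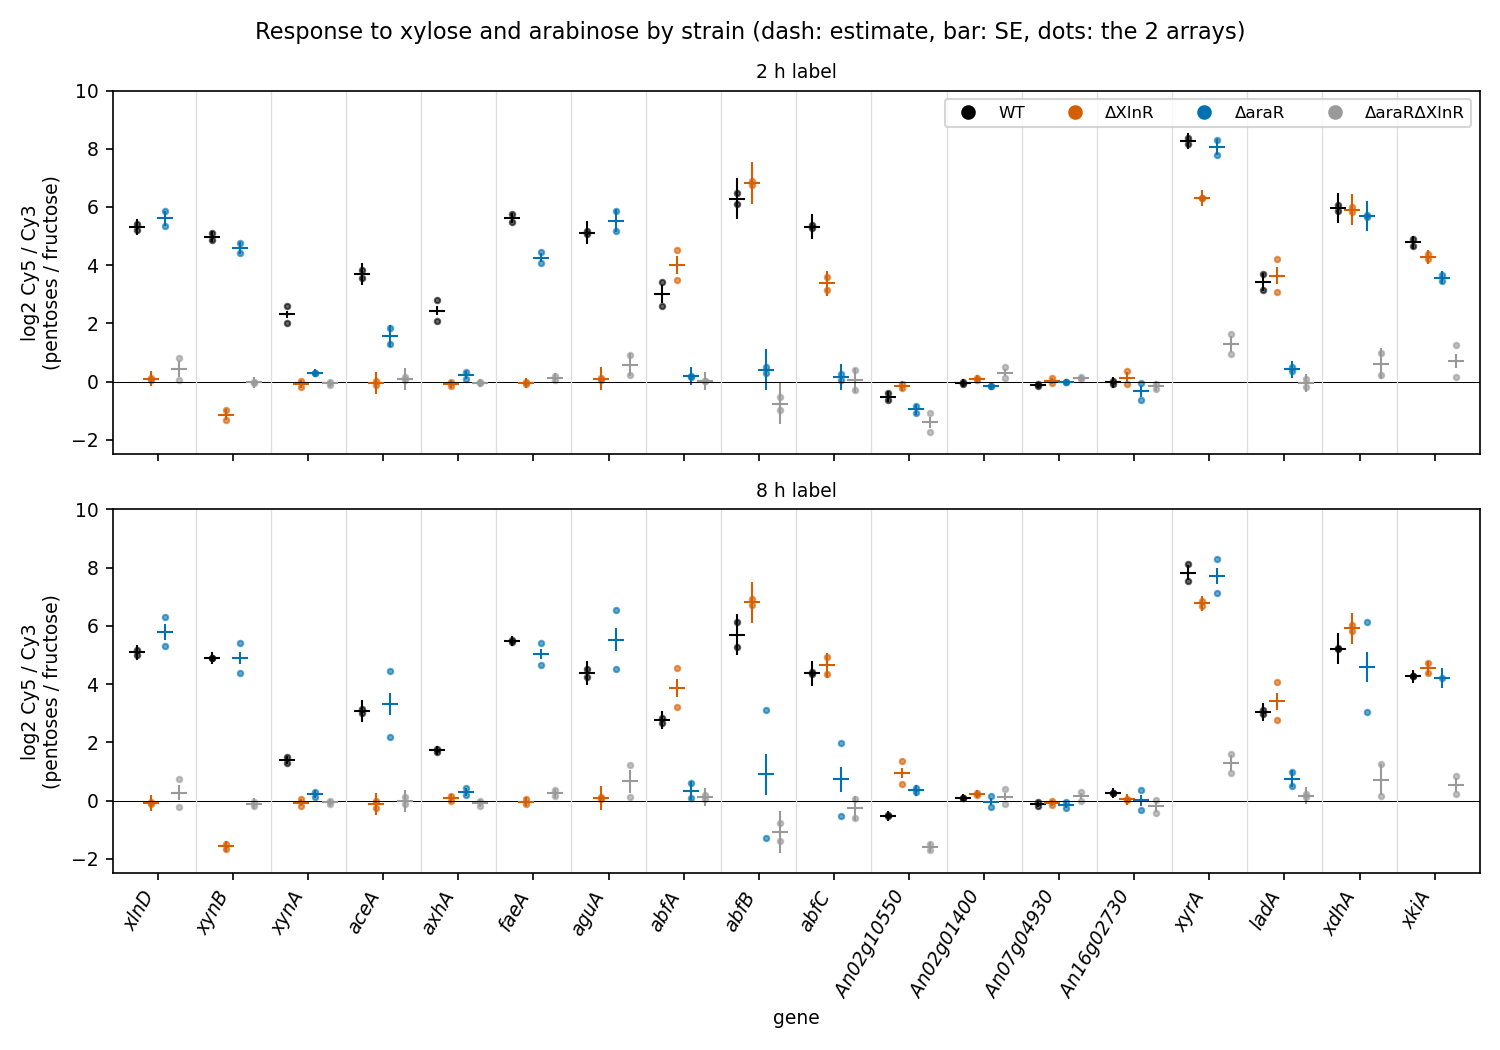
Log2 ratio of pentose over fructose signal of genes of xylan, arabinan and pentose breakdown in the 4 strains at 2 h and 8 h; dots are the 2 arrays of a group, dashes the fitted means and bars the SE. The gene xyrA reached 8.26 in WT and 8.05 in ΔaraR at 2 h, 6.31 in ΔXlnR, and 1.30 in ΔaraRΔXlnR.

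In ΔXlnR the pentose genes still rose and no xylan gene was called higher. At 2 h xyrA rose by 6.31 ± 0.27 (adjusted p = 2.52e-06), xdhA by 5.91 ± 0.53, xkiA by 4.28 ± 0.23, ladA by 3.64 ± 0.30 and abfA by 4.01 ± 0.31, and abfB rose at least 102-fold. At 8 h xyrA (6.77 ± 0.27), xkiA (4.55 ± 0.23), abfA (3.87 ± 0.31) and abfC (4.64 ± 0.43) were up and abfB at least 100-fold. All 4 pentose genes were called higher at both times, as were 3 of 7 arabinan genes at 2 h and 4 of 7 at 8 h. None of the xylan genes rose at either time by limma's test (0 higher at an unadjusted p under 0.05). The xylan genes xlnD, faeA, aguA, aceA, xynA and axhA were not called. The gene xynB fell by 1.13 ± 0.20 at 2 h (adjusted p = 0.0768 without ΔXlnR 2 h number 1 and 0.113 without number 2) and by 1.57 ± 0.20 at 8 h (0.0647 without ΔXlnR 8 h number 1). The rise of gpdA was 1.52 ± 0.19 at 2 h (adjusted p = 0.0933 with arrays scaled by their medians). Calls numbered 995 of 9172 genes at 2 h (724 higher, 271 lower, but 233 higher and 230 lower with arrays scaled by their medians), 84 without number 1 and 285 without number 2. At 8 h they numbered 1065 of 9172 (698 higher, 367 lower, but 217 higher and 821 lower with arrays scaled by their medians), 54 without number 1 and 163 without number 2. On scan days 1 and 2 xyrA was at 6.29 and 6.32 at 2 h, and at 6.69 and 6.86 at 8 h.

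In ΔaraR the pattern was largely the other way around, with most xylan genes rising and no arabinan gene called higher. The xylan genes xynA and axhA rose little. On numbers 1 and 2 xynA was at 0.31 and 0.29 at 2 h, and at 0.14 and 0.30 at 8 h. The ratios of axhA were 0.34 and 0.10 at 2 h, and 0.41 and 0.18 at 8 h. At 2 h xyrA rose by 8.05 ± 0.27 (adjusted p = 2.05e-07), xlnD by 5.60 ± 0.27, aguA by 5.52 ± 0.40, xynB by 4.59 ± 0.20 and xkiA by 3.57 ± 0.23, and faeA at least 17.1-fold. At 8 h xyrA (7.71 ± 0.27), xlnD (5.79 ± 0.27), aguA (5.52 ± 0.40), faeA (5.03 ± 0.16), xynB (4.90 ± 0.20), aceA (3.32 ± 0.38), aglB (4.42 ± 0.27), bgl1 (3.25 ± 0.33) and eglA (3.16 ± 0.35) had risen. Of 7 xylan genes 4 rose at 2 h (6 adjusted over the list alone) and 5 at 8 h, and of the 4 pentose genes 3 rose at each time (4 at 8 h adjusted over the list alone), with ladA not called and xkiA measured at 8 h on number 2 alone. None of the 7 arabinan genes was called higher by limma's test at either time (0 higher at an unadjusted p under 0.05). On the 8 h arrays of numbers 1 and 2 the ratios of abfC were -0.52 and 1.96, and that of abfB was -1.28 on number 1 and positive on number 2, so whether they respond at 8 h is open. Those of xdhA were 3.05 and 6.13, those of aceA 2.17 and 4.46, and those of aguA 4.50 and 6.54. The residual variance of a gene was shared by all groups in the fit. These gaps therefore raised the SE and p-values of abfB, abfC, xdhA, aceA and aguA in every response and comparison of responses. The arabinan gene An02g10550 was lower at 2 h (-0.96 ± 0.18, adjusted p = 0.142 without ΔaraR 2 h number 1 and 0.312 without number 2). On the 8 h array of number 1 the fructose signals of 10 genes were raised. They lay more than 1 (log2) above those of the 2 h array of that number. For 9 of them this held over both arrays of number 2 too, which lowers their 8 h ratios on number 1. Among the 10 were xyrA, xdhA, abfB, abfC and An14g01790, but not aceA or aguA. The Cy5 signals of abfB and abfC there (7.28 and 7.11) lay above their Cy3 signals on the 2 h array (5.99 and 6.26). The missing calls of abfB and abfC at 8 h therefore do not show that no response was left. Calls numbered 149 of 9173 genes at 2 h (63 higher, 86 lower), 74 without number 1 and 16 without number 2. At 8 h they numbered 1448 of 9173 (748 higher, 700 lower, but 247 higher and 569 lower with arrays scaled by their medians), 752 without number 1 and 466 without number 2. On scan days 1 and 2 xlnD was at 5.36 and 5.85 at 2 h, and at 5.29 and 6.29 at 8 h.

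In ΔaraRΔXlnR no xylan gene was called and xyrA rose. On the arrays labelled 2 h, 0 of 7 xylan genes were called by limma's test (0 at an unadjusted p under 0.05), and 1 of 7 arabinan genes was lower. Among the pentose genes xyrA alone was called (2 adjusted over the list alone), with a rise of 1.30 ± 0.27 (adjusted p = 0.353 without number 2). On the arrays labelled 8 h xyrA rose by 1.28 ± 0.27 (adjusted p = 0.527 without number 1), and 0 of 7 xylan genes were called (0 at an unadjusted p under 0.05). The gene An02g10550 fell by 1.40 ± 0.18 and 1.59 ± 0.18 under the labels 2 h and 8 h. Calls numbered 262 of 9173 genes under the label 2 h (159 higher, 103 lower, but 52 higher and 15 lower with arrays scaled by their medians), 936 without number 1 and 26 without number 2. They numbered 362 of 9172 under the label 8 h (210 higher, 152 lower, but 71 higher and 11 lower with arrays scaled by their medians), 27 without number 1 and 1176 without number 2. On scan days 1 and 2 xyrA was at 0.96 and 1.64 under the label 2 h, and at 1.60 and 0.96 under the label 8 h. The time labels of these 4 arrays are in doubt. Across genes, which are not independent replicates, the ratios of 2 h number 1 correlated with 8 h number 2 at r = 0.722 and those of 8 h number 1 with 2 h number 2 at r = 0.825. Arrays with a shared label had r = 0.329 at 2 h and 0.404 at 8 h. On 2 h number 2 and 8 h number 1 aguA was at 0.93 and 1.23 and xlnD at 0.82 and 0.75. On 2 h number 1 and 8 h number 2 aguA was at 0.23 and 0.11 and xlnD at 0.06 and -0.21. The other xylan genes stayed at 0.35 or less on all 4 arrays. Means within a label joined 1 array of each kind, so the missing calls do not show that no response was left.

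**Figure D3:**
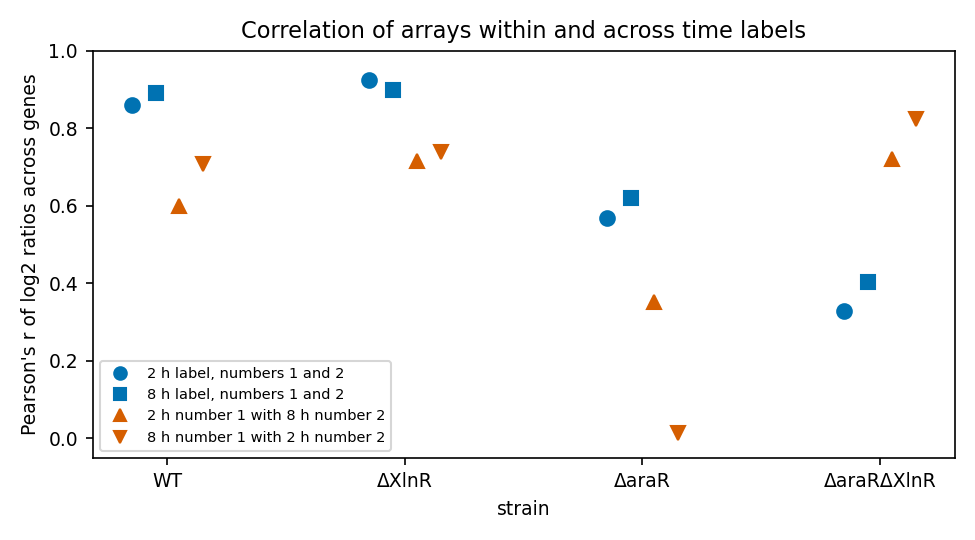
Pearson correlation across genes of the log2 ratios of pairs of arrays within each strain, for arrays of numbers 1 and 2 that share a time label (blue) or carry different labels (orange); 1 point per pair. In ΔaraRΔXlnR the pairs with the same label reached 0.329 and 0.404, against 0.859 and 0.891 in WT.

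The comparison of ΔXlnR with WT asked which responses differed between these strains. At 2 h xynB differed by -6.11 ± 0.28 (adjusted p = 2.10e-06), xlnD by -5.20 ± 0.38, aguA by -5.02 ± 0.56 and xynA by -2.39 ± 0.18. The Cy5 signals of faeA, aceA and axhA were at least 49.9-fold, 15.5-fold and 5.68-fold lower. The genes lacA (-2.81 ± 0.44) and aglB (-2.44 ± 0.38) also responded less. All 7 xylan genes had lower responses in ΔXlnR at both times, and 0 of 7 arabinan genes differed at 2 h by limma's test (2 at an unadjusted p under 0.05). Within numbers 1 and 2 abfC was nevertheless lower at 2 h (-1.66 and -2.24), while abfA (1.08 and 0.89) and abfB (0.80 and 0.27) were higher. A dependence of abfC on XlnR at 2 h is therefore left open. At 8 h 1 arabinan gene was called, An02g10550 (1.48 ± 0.26), with differences of -2.05 in Cy3 and -0.57 in Cy5. The call was lost without WT 8 h number 1 or 2 (adjusted p = 0.0690 or 0.0586), without ΔXlnR 8 h number 1 (0.0676) and with arrays scaled by their medians (0.174). At 8 h xynB differed by -6.47 ± 0.28, xlnD by -5.17 ± 0.38, aguA by -4.29 ± 0.56 and xynA by -1.46 ± 0.18. There the Cy5 signals of faeA and axhA were at least 60.4-fold and 3.73-fold lower.

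Of the pentose genes xyrA was lower in ΔXlnR than in WT at 2 h (-1.96 ± 0.39). The call was lost without WT 2 h number 1 or 2 (adjusted p = 0.0716 or 0.0687) and without ΔXlnR 2 h number 1 or 2 (0.107 or 0.0819). At 8 h xyrA was not called (-1.06 ± 0.39, adjusted p = 0.153), and xdhA, xkiA and ladA were not called at either time. Higher responses than in WT were those of An11g06970 (4.49 ± 0.45), An07g00760 (3.54 ± 0.25) and An08g07310 (3.42 ± 0.44) at 2 h, and of An08g10860 (4.42 ± 0.58) and dhbD (An07g02050, 3.68 ± 0.41) at 8 h. That of An04g08150 at 8 h (4.60 ± 0.29) came with a difference of -4.49 in Cy3 and of 0.12 in Cy5, so it reflects the fructose level. The Cy3 and Cy5 parts were computed after the differences were seen. At 2 h 581 of 9172 genes differed (354 higher, 227 lower, but 108 higher and 112 lower with arrays scaled by their medians), 229 without WT number 1, 161 without ΔXlnR number 1 and 241 without ΔXlnR number 2. At 8 h 544 of 9170 differed (332 higher, 212 lower, but 109 higher and 462 lower with arrays scaled by their medians), 164 and 197 without WT number 1 and 2, and 153 and 177 without ΔXlnR number 1 and 2. Both strains shared slides of the same number, and within the slides of numbers 1 and 2 xynB differed by -5.82 and -6.40 at 2 h, and by -6.56 and -6.38 at 8 h.

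The comparison of ΔaraR with WT asked the same of AraR. At 2 h abfB differed by -5.88 ± 1.00 (adjusted p = 0.00429), abfC by -5.17 ± 0.61, ladA by -2.99 ± 0.42 and An03g01050 by -5.53 ± 0.70. The Cy5 signal of abfA was at least 9.29-fold lower. Of the xylan genes 4 of 7 also responded less, among them axhA (-2.21 ± 0.21) and xynA (-2.01 ± 0.18), while xlnD, aguA, xynB, xyrA and xdhA were not called. At 8 h 2 of 7 xylan genes were lower, and of the 4 pentose genes 2 were lower at 2 h and 1 at 8 h. Within numbers 1 and 2 at 8 h xynA differed by -1.36 and -0.98 and axhA by -1.26 and -1.59. The arabinan list had 3 of 7 genes lower at 2 h and 3 of 7 at 8 h (there 1 was higher adjusted over the list alone). At 8 h abfB was at -4.80 ± 1.00, abfC at -3.65 ± 0.61 and ladA of the pentose list at -2.28 ± 0.42. Those 3 calls were lost without WT 8 h number 1 (adjusted p = 0.129, 0.0887 and 0.133) and without WT 8 h number 2 (0.197, 0.0734 and 0.0958), and that of ladA also without ΔaraR 8 h number 1 (0.0791). For abfB and abfC the SE includes the gap between the ΔaraR 8 h arrays of numbers 1 and 2. On the WT 8 h arrays of numbers 1 and 2 abfB was at 5.28 and 6.13 and abfC at 4.42 and 4.34. Their lost calls therefore do not by themselves show that the WT arrays disagreed. At 8 h An14g01790 (-5.28 ± 0.50) stayed lower in every leave-one-out, but like abfB and abfC it had a raised fructose signal on the ΔaraR 8 h array of number 1. The 8 h differences of these genes from WT may therefore be too large.

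Higher responses in ΔaraR than in WT were those of An02g04220 (3.07 ± 0.42) and An08g07420 (2.88 ± 0.46) at 2 h and of An07g06240 (3.37 ± 0.36) at 8 h. Those of An04g08150 (4.72 ± 0.29) and An07g01320 (3.19 ± 0.33) at 8 h reflect fructose levels, with differences of -4.45 and -6.28 in Cy3 and of 0.28 and -3.08 in Cy5. At 2 h 1291 of 9173 genes differed (791 higher, 500 lower), 348 without WT number 1 and 338 without ΔaraR number 2. At 8 h 299 of 9171 differed (140 higher, 159 lower, but 52 higher and 131 lower with arrays scaled by their medians), 76 and 93 without WT number 1 and 2, and 166 without ΔaraR number 2. No slide held both strains, so slide and strain cannot be told apart here. Each scan day held both, and abfC differed by -5.21 and -5.13 on them at 2 h, and by -4.93 and -2.37 at 8 h.

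Against WT the strain ΔaraRΔXlnR had lost or weaker responses among the xylan, arabinan and pentose genes. On the arrays labelled 2 h abfB differed by -7.04 ± 1.00 (adjusted p = 0.00284), xyrA by -6.96 ± 0.39, xdhA by -5.34 ± 0.74 and abfC by -5.28 ± 0.61. Next came xlnD with -4.86 ± 0.38, xkiA with -4.08 ± 0.33 and ladA with -3.47 ± 0.42. The Cy5 signals of faeA, lacA, aceA and abfA were at least 47.5-fold, 23.3-fold, 15.0-fold and 9.35-fold lower. All 7 xylan and 4 pentose genes were lower under both labels, and of 7 arabinan genes 3 were lower at 2 h (4 adjusted over the list alone) and 4 at 8 h. On the arrays labelled 8 h the differences of xyrA (-6.55 ± 0.39), abfB (-6.79 ± 1.00), xynB (-5.01 ± 0.28), xlnD (-4.82 ± 0.38), An15g06810 (-4.98 ± 0.81) and cbhB (-1.86 ± 0.24) held in every leave-one-out. Higher responses were those of An04g03530 (4.29 ± 0.48 at 2 h, 5.07 ± 0.48 at 8 h) and An08g09700 (4.12 ± 0.66 and 4.67 ± 0.66). Under the label 2 h 1047 of 9173 genes differed (536 higher, 511 lower, but 267 higher and 141 lower with arrays scaled by their medians), 195 without WT number 1 and 506 without ΔaraRΔXlnR number 2. Under the label 8 h 940 of 9170 differed (391 higher, 549 lower, but 99 higher and 222 lower with arrays scaled by their medians), 214 and 359 without WT number 1 and 2, and 318 and 1527 without ΔaraRΔXlnR number 1 and 2. No slide held both strains, but ΔaraR shared its slides with ΔaraRΔXlnR. On slides 2 and 4 at 2 h xyrA was at 8.31 and 7.79 in ΔaraR against 0.96 and 1.64 in ΔaraRΔXlnR, and xlnD at 5.36 and 5.85 against 0.06 and 0.82, so the slide does not account for their lost responses. For arabinan genes slide and strain cannot be told apart. Within scan days xyrA differed by -7.21 and -6.71 at 2 h, and by -5.95 and -7.16 at 8 h.

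The WT difference between 8 h and 2 h asked which responses went on changing. Of the 4 pentose genes limma called 0 (0 at an unadjusted p under 0.05), but within numbers 1 and 2 all had lower ratios at 8 h: xyrA (-0.62 and -0.24), xdhA (-0.65 and -0.84), xkiA (-0.40 and -0.63) and ladA (-0.59 and -0.17). Of the xylan genes xynA alone was called (2 adjusted over the list alone), with -0.92 ± 0.18. The call was lost when an array was left out (adjusted p = 0.166 without WT 2 h number 1, 0.106 without WT 8 h number 1 and 0.283 without WT 8 h number 2). The genes An14g02490 (2.14 ± 0.19, adjusted p = 4.65e-04) and An12g10430 (2.12 ± 0.17) rose between 2 h and 8 h and An07g06240 fell by 3.13 ± 0.36, and these held in every leave-one-out. In all 192 of 9171 genes differed (110 higher, 82 lower, but 126 higher and 33 lower with arrays scaled by their medians), 38 and 111 without WT 2 h number 1 and 2, and 40 and 25 without WT 8 h number 1 and 2. With strain and number as a random block, a setting chosen after seeing the data, the count was 480 (298 higher, 182 lower), again with 0 pentose genes (adjusted p from 0.493 to 0.689, 0 at an unadjusted p under 0.05), and the WT arrays of a number deviated together (r = 0.657 across genes). That block used a single correlation (0.277) for all strains, so it was not a paired test of WT. Whether the pentose genes fell between 2 h and 8 h is open. On scan days 1 and 2 xynA differed by -1.12 and -0.73.

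The test of non-additivity asked whether the change of a response in ΔaraRΔXlnR differed from the sum of its changes in ΔXlnR and ΔaraR. The gene xyrA departed from that sum by -4.79 ± 0.55 on the arrays labelled 2 h (adjusted p = 0.00211) and by -5.37 ± 0.55 on those labelled 8 h. At 8 h xkiA (-3.95 ± 0.52) was lower than the sum too, with the ΔaraR 8 h value from number 2 alone. For aglB (-4.37 ± 0.53) and An02g10550 (-3.43 ± 0.36) most of the departure lay in the fructose signals, at 3.80 and 3.04 in Cy3 against -0.56 and -0.39 in Cy5. Of the 4 pentose genes 3 were lower than additive at each time, and of the 7 xylan genes 3 were higher at 2 h (5 adjusted over the list alone) and 2 at 8 h (3 adjusted over the list alone). A response near 0 in ΔXlnR has nothing left to lose, so values above the sum are to be expected where ΔaraR also responded less. Of the 3 nitrate genes niaD was higher than additive at 2 h (2 genes adjusted over the list alone), by 4.43 ± 1.06. The call of niaD was lost without WT number 1 (adjusted p = 0.169), ΔXlnR number 1 or 2 (0.121 or 0.147), ΔaraR number 2 (0.189) or ΔaraRΔXlnR number 1 (0.0730). Calls numbered 379 of 9172 genes at 2 h (180 higher, 199 lower, but 63 higher and 45 lower with arrays scaled by their medians): 98 without WT number 1, 73 and 77 without ΔXlnR number 1 and 2, 72 without ΔaraR number 2 and 575 without ΔaraRΔXlnR number 1. At 8 h they numbered 516 of 9169 (171 higher, 345 lower, but 757 higher and 125 lower with arrays scaled by their medians): 197 and 140 without WT number 1 and 2, 114 and 170 without ΔXlnR number 1 and 2, 285 without ΔaraR number 2, and 324 without ΔaraRΔXlnR number 1. Within scan days xyrA departed by -5.47 and -4.11 at 2 h, and by -4.66 and -6.09 at 8 h.

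The Cy3 channel gave the fructose levels of each strain, and the 3 deletion strains differed from WT before any pentose was added. The protease gene pepA (An14g04710) differed from WT by -5.72 ± 0.30 in ΔXlnR (adjusted p = 2.69e-04), -3.93 ± 0.30 in ΔaraR and -5.02 ± 0.30 in ΔaraRΔXlnR. The level of glaA differed by -2.03 ± 0.11 in ΔXlnR and -2.01 ± 0.11 in ΔaraR, and in ΔaraRΔXlnR it was at least 4.04-fold lower. Lower in all 3 strains were also aglB (-3.12 ± 0.31, -3.36 ± 0.31 and -2.38 ± 0.31) and An07g03340 (-3.68 ± 0.20, -3.80 ± 0.20 and -3.10 ± 0.20). The nitrate transporter gene crnA was higher (1.91 ± 0.26, 2.51 ± 0.26 and 1.71 ± 0.26), with calls lost when both arrays of a strain and number were left out. In ΔXlnR its adjusted p was then 0.0553 without WT number 1, and 0.0580 and 0.0709 without ΔXlnR number 1 and 2. In ΔaraRΔXlnR it was 0.0526 without WT number 1 and 0.0519 without ΔaraRΔXlnR number 2. The xylosidase gene xlnD was lower in the strains without XlnR (-1.65 ± 0.15 in ΔXlnR and -1.47 ± 0.15 in ΔaraRΔXlnR) and not called in ΔaraR (-0.05 ± 0.15). Of 6 conidiation genes 3 were lower in ΔXlnR, 4 in ΔaraR and 4 in ΔaraRΔXlnR (4 in each adjusted over the list alone), and of 4 glyoxylate cycle genes 2 were lower in each (3 in ΔXlnR adjusted over the list alone). Calls numbered 841 of 9173 genes in ΔXlnR (254 higher, 587 lower), 606 in ΔaraR (172 higher, 434 lower) and 1798 in ΔaraRΔXlnR (980 higher, 818 lower). Leaving out both arrays of a strain and number, which was chosen after seeing the data, gave 402 and 459 in ΔXlnR without WT number 1 and 2, and 269 and 290 without ΔXlnR number 1 and 2. It gave 268 and 383 in ΔaraR without WT number 1 and 2, 678 and 1079 in ΔaraRΔXlnR without WT number 1 and 2, and 668 and 863 without ΔaraRΔXlnR number 1 and 2. Each strain had 2 values here, since the Cy3 signals of its 2 h and 8 h arrays of 1 number correlated across genes at r between 0.995 and 0.999, against 0.972 to 0.988 between numbers. Within scan days 1 and 2 xlnD differed by -1.41 and -1.88 in ΔXlnR, 0.14 and -0.24 in ΔaraR, and -1.40 and -1.55 in ΔaraRΔXlnR. ΔXlnR shared its slides with WT, while for ΔaraR and ΔaraRΔXlnR slide and strain cannot be told apart.

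Gene lists were also tested as sets by camera with a preset correlation, and most calls did not outlast a correlation estimated from these arrays. The xylan list was called higher in WT (adjusted p = 2.03e-13 at 2 h and 7.17e-14 at 8 h; 0.0278 and 0.0251 with an estimated correlation) and in ΔaraR (2.25e-15 at 2 h and 7.66e-10 at 8 h; 0.0182 and 0.0511 with an estimated correlation). It was called lower against WT in ΔXlnR (2.91e-19 and 3.09e-16; 0.00878 and 0.0153 with an estimated correlation) and ΔaraRΔXlnR (2.51e-14 and 4.33e-13; 0.0227 and 0.0300 with an estimated correlation). In ΔaraR against WT it was called lower at 2 h (adjusted p = 0.00717) but not with an estimated correlation (adjusted p = 0.350). The pentose list was called higher in WT (6.21e-06 and 1.47e-06; 0.0396 and 0.0319 with an estimated correlation) and in ΔXlnR (1.05e-06 and 1.35e-06; 0.0482 and 0.0506 with an estimated correlation). It was also called higher in ΔaraR (4.98e-07 and 1.44e-04; 0.0239 and 0.0610 with an estimated correlation), and lower in ΔaraRΔXlnR against WT (5.43e-06 and 9.69e-06; 0.0385 and 0.0466 with an estimated correlation). The arabinan list was not called in WT at 2 h (adjusted p = 0.0744; its median was -0.03 and its mean 1.99) and was called at 8 h (0.0475; 0.233 with an estimated correlation). It was lower against WT in ΔaraR at 2 h (0.0158; 0.350 with an estimated correlation) and in ΔaraRΔXlnR (0.00956 and 0.00268; 0.165 and 0.0957 with an estimated correlation). In the non-additivity at 2 h the xylan list (1.14e-04) and the nitrate list (0.0173) were called higher and the pentose list lower (0.00532), none with an estimated correlation (0.155 for each). The list of cellulases and other hydrolases was called higher in WT (3.44e-05 and 1.47e-06), with an adjusted p = 0.0761 and 0.0375 with an estimated correlation. The median, mean and test of a list differed in sign for the pentose list in ΔXlnR against WT at 8 h (median 0.33, mean 0.07, test lower). They also differed for lists not called in the ΔaraRΔXlnR responses, the arabinan list at 2 h (median 0.03, mean -0.26, test lower) and the xylan list at 8 h (median -0.01, mean 0.13, test higher). The pentose phosphate list was called higher in WT at 2 h (adjusted p = 0.0279; 0.125 with an estimated correlation), and the glycolysis list too (0.0103; 0.268 with an estimated correlation).

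In further lists, of the 4 starch and inulin genes 1 was lower in WT at 2 h (2 adjusted over the list alone) and 2 at 8 h (there 1 was higher adjusted over the list alone). Of the 2 measured sugar transporter genes, too few for a set test, mstA (An12g07450) was lower at 2 h by 1.29 ± 0.31. The call was lost without WT 2 h number 1 (adjusted p = 0.279). Of 9 pectin genes 1 was higher and 2 lower at 2 h, and of 5 carbon starvation genes 2 were higher. Of 5 folding and secretion genes tigA (An18g02020) alone was higher, against 2 adjusted over the list alone (1.27 ± 0.22, adjusted p = 0.0828 without WT 2 h number 1). Of the 4 glyoxylate cycle genes and 6 conidiation genes, limma called 0 at 2 h (0 and 1 at an unadjusted p under 0.05). Of the 3 nitrate genes, limma called 0 in WT at 2 h (0 at an unadjusted p under 0.05), and niaD fell by 2.26 ± 0.53 in ΔXlnR at 2 h (adjusted p = 0.210 and 0.234 without number 1 or 2). Set tests of fructose levels called the conidiation list lower in all 3 strains (adjusted p = 0.00133, 1.68e-04 and 0.00792; 0.183, 0.154 and 0.512 with an estimated correlation). They also called the starvation list lower in ΔXlnR and ΔaraR (0.0104 and 0.0143; 0.172 and 0.154 with an estimated correlation), as well as the glyoxylate list (0.00258 and 0.00324; 0.172 and 0.154 with an estimated correlation). Relative to the sizes above, scaling arrays by their medians moved the median of all genes by 0.12 in the WT response at 8 h, and by -0.12 in that of ΔXlnR at 8 h. It moved that median by -0.28 and -0.23 in the differences of ΔXlnR and ΔaraR from WT at 8 h, by 0.11 in the WT time difference, and by 0.15 and 0.42 in the non-additivity at 2 h and 8 h.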

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

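Of the tests below, all those in the 1st pattern, those of another RNA and of raised probes above Cy5 in the 2nd, and that of a single WT culture in the 3rd were chosen after the result was seen, and so was the reading of the simulation.

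Counts singled out because a test of the difference showed 2 groups' responses to differ were 581 genes at 2 h and 544 at 8 h for ΔXlnR against WT, 1291 and 299 for ΔaraR against WT, and 1047 and 940 for ΔaraRΔXlnR against WT. By such a test 192 genes also differed between 8 h and 2 h in WT, and 379 genes at 2 h and 516 at 8 h departed from additivity. No group held enough arrays to look for a single array far from the others.

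In ΔaraRΔXlnR the arrays resembled those with the other time label more than their partner. A shared slide as the cause is argued against, since arrays sharing a slide had a mean r of 0.474 across genes, under the 0.773 of arrays sharing neither slide nor label. So is weak signal, since among 5845 probes well above background in both channels on all arrays the lowest r across labels still exceeded the highest within them by 0.305. A wrong label may be the cause, and no test here decides it: the r = -0.558 across genes of the differences between numbers at 2 h and 8 h follows from the pattern itself. The mean time difference of the other strains had r = 0.143 with that of number 1 and r = -0.145 with that of number 2. Taken singly those strains gave r from 0.00493 to 0.145 and from -0.182 to -0.0253, and their time differences had r from -0.24 to 0.24 among themselves. Each strain had a positive r with number 1 and a negative one with number 2, but the values were small. The strains' own time differences did not agree among themselves either. An exchange on number 1 and one on number 2 therefore cannot be told apart. Cultures that advanced at different speeds would look alike and were not tested, so the time of these 4 arrays stays open.

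On the ΔaraR 8 h array of number 1, 10 genes had a Cy3 signal raised by more than 1 (log2) over the 2 h array of that strain and number, among them abfB, abfC, xdhA, xyrA, An03g01050 and dhbD. The Cy5 signal of the same array cannot explain all of them, since 8 of the 10 had a Cy3 signal above their Cy5 signal. It may add to the rest, judging by 2 probes bright in that Cy5 channel but not in that of ΔXlnR at 8 h. Their median excess was 0.842 over the mean of the other 3 ΔaraR arrays. RNA of another sample may have reached this channel. All 5 probes bright in the Cy5 channel of ΔXlnR at 8 h but not in that of ΔaraR were raised. Their median excess was 2.08 against an SD of 0.243 over all probes. The Cy5 signals of WT played no part in that choice, so it does not single out ΔXlnR as the source. A response of ΔaraR itself to pentoses was not tested, and the 8 h ratios of 9 of these genes in ΔaraR are too low on number 1 if the excess is not from its fructose RNA. The 10th, An11g06160, was not raised by that much over the arrays of number 2.

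On fructose 371 genes differed from WT the same way in all 3 deletion strains (63 higher, 308 lower), among them An07g01320, pepA and glaA lower and leu2A higher. For genes called the same way in ΔaraR and ΔaraRΔXlnR, ΔXlnR against WT had a signed median of at least 1.04 on each slide that held both. It used the WT values that had picked the genes, which can raise it, so it decides nothing alone. Genes at least 2-fold apart from WT in both ΔaraR and ΔaraRΔXlnR on the arrays of 1 number were also measured on the other number. There ΔXlnR and WT shared a slide, and their difference had a signed median of at least 1.26. That argues against slides as the whole cause and against a single deviating WT value. Unchanged strains simulated against the same WT values gave at most 0 shared genes in 100 simulations, but also 0 calls per comparison, so they exclude nothing. Independent lists would share 2.99 genes, and part of the excess may come from the shared WT values. A biological difference may remain, such as another parent strain or another state of the fructose cultures, and neither was tested.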

How the results depend on the processing

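Chosen after seeing the data were the settings without the 4 ΔaraRΔXlnR arrays, with strain and number as a random block, with the times of ΔaraRΔXlnR exchanged, and, for fructose levels, without both arrays of a strain and number. Of 6801 values of named genes under an alternative, 5816 kept direction and call, 984 kept the direction but lost the call, and 1 changed sign: lacA in ΔXlnR against WT at 8 h, which was 0.10 with processed signals (adjusted p = 0.898). Blocks, filters and the fold limit mostly leave estimates as they are, so they could hardly turn a direction. The cause was not tested, here or below, except where the construction of a setting shows it. Of 67 list calls by camera 52 were lost with an estimated correlation.

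All 20 counts stayed within 1.5 times without background subtraction, and with the replicate block, for example 2061 in the WT response at 2 h, 740 in ΔXlnR against WT at 2 h and 1175 in the fructose levels of ΔXlnR. The replicate block lost 2 list calls and gained 3. Over 28 pairs of groups the differences between numbers correlated across genes at r from -0.56 to 0.69, with 13 above 0.1. Within a strain, between its 2 h and 8 h groups, r was 0.657 (WT), 0.543 (ΔXlnR), 0.694 (ΔaraR) and -0.558 (ΔaraRΔXlnR), so arrays of a strain and number deviated together in 3 strains. The 3 fructose counts stayed within that range under quantile normalization of Cy3 alone.

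With arrays scaled by their medians, 13 of 17 counts went down and 1 up by more than 1.5 times. Responses then had 967 calls (WT 2 h), 825 (WT 8 h), 463 (ΔXlnR 2 h), 52 (ΔaraR 2 h), 816 (ΔaraR 8 h), 67 (ΔaraRΔXlnR 2 h) and 82 (ΔaraRΔXlnR 8 h). Differences from WT had 220 (ΔXlnR 2 h), 484 and 183 (ΔaraR 2 h and 8 h) and 408 and 321 (ΔaraRΔXlnR 2 h and 8 h), and the non-additivity 108 (2 h) and 882 (8 h). The share of calls that were higher also moved by more than 10 points, to 75.6% (WT 8 h), 50.3% (ΔXlnR 2 h), 20.9% (ΔXlnR 8 h), 30.3% (ΔaraR 8 h), 77.6% (ΔaraRΔXlnR 2 h) and 86.6% (ΔaraRΔXlnR 8 h) in the responses. In the differences from WT it moved to 49.1% and 19.1% (ΔXlnR 2 h and 8 h), 28.4% (ΔaraR 8 h) and 65.4% and 30.8% (ΔaraRΔXlnR 2 h and 8 h), in the WT time difference to 79.2%, and in the non-additivity to 58.3% (2 h) and 85.8% (8 h). The balance of higher and lower calls is therefore uncertain in these results.

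Processed signals gave 651 and 704 calls in the ΔaraRΔXlnR responses (2 h and 8 h), 104 in the WT time difference, and 1271 and 976 in the fructose levels of ΔXlnR and ΔaraR, with 57.7% higher in ΔaraR against WT at 8 h and 43.3% in the WT time difference. The value table gave 537 (ΔaraRΔXlnR response 2 h), 364 (ΔXlnR against WT 2 h, 50% higher), 844 (ΔaraR against WT 2 h), 106 (WT time difference, 42.5% higher) and 229 (non-additivity 2 h, 58.1% higher), with 61.9% higher in ΔaraR against WT at 8 h. It was not used for fructose levels, as it holds ratios.

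No filter on dim probes gave 168 and 241 in the ΔaraRΔXlnR responses. The strict filter, which tests 5845 genes, gave 337 and 280 (ΔXlnR against WT 2 h and 8 h), 78 (ΔaraR against WT 8 h), 613 (ΔaraRΔXlnR against WT 8 h), 47 (WT time difference), 225 and 308 (non-additivity) and 424, 280 and 1048 (fructose levels of ΔXlnR, ΔaraR and ΔaraRΔXlnR). Whether signal over background caused these shifts was not tested.

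Asking for at least a 2-fold change, which can only remove calls, left 605 and 419 (WT response 2 h and 8 h), 395 and 378 (ΔXlnR), 73 and 368 (ΔaraR) and 113 and 134 (ΔaraRΔXlnR). It left 335 and 330 (ΔXlnR against WT), 716 and 164 (ΔaraR against WT), 583 and 537 (ΔaraRΔXlnR against WT), 119 (WT time difference), and 444, 321 and 729 (fructose levels of ΔXlnR, ΔaraR and ΔaraRΔXlnR).

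Fitting only the groups of a comparison leaves few degrees of freedom and moved 17 of 17 counts, 5 up and 12 down. Responses had 1223 and 2712 (WT), 3242 and 2783 (ΔXlnR) and 8 (ΔaraR 2 h) calls. limma called 0 genes in ΔaraR at 8 h (1916 at an unadjusted p under 0.05) and 0 in ΔaraRΔXlnR at 2 h and 8 h (788 and 701). Differences from WT had 1008 and 1690 (ΔXlnR), 350 and 19 (ΔaraR) and 58 and 72 (ΔaraRΔXlnR), the WT time difference 19 and the non-additivity 117 and 208.

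Slide as a fixed block gave 581 in the non-additivity at 2 h, and slide as a random block 1417 in the fructose levels of ΔXlnR. Strain and number as a random block gave 480 in the WT time difference. Without the 4 ΔaraRΔXlnR arrays there were 1642 and 1919 (ΔXlnR response), 479 (ΔaraR response 2 h), 1063 and 1095 (ΔXlnR against WT), 487 (ΔaraR against WT 8 h) and 307 (WT time difference), all more.

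Exchanging the times on the ΔaraRΔXlnR arrays of number 1 gave 2675 (response 2 h), 3118 (against WT 2 h), and 1575 and 1333 (non-additivity). Exchanging them on number 2 gave 492 and 2675 (response 2 h and 8 h), 2660 (against WT 8 h), and 1040 and 1391 (non-additivity).

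Leaving out 1 array at a time, with the lone array of its group assumed to vary like the other groups, gave response counts from 485 to 1477 (WT 2 h), 242 to 447 (WT 8 h), 84 to 285 (ΔXlnR 2 h), 54 to 163 (ΔXlnR 8 h), 16 to 74 (ΔaraR 2 h), 466 to 752 (ΔaraR 8 h), 26 to 936 (ΔaraRΔXlnR 2 h) and 27 to 1176 (ΔaraRΔXlnR 8 h). Differences from WT ran from 161 to 442 and 153 to 197 (ΔXlnR 2 h and 8 h), 338 to 1201 and 76 to 261 (ΔaraR), and 195 to 1263 and 214 to 1527 (ΔaraRΔXlnR). The WT time difference ran from 25 to 111, and the non-additivity from 72 to 575 (2 h) and 114 to 738 (8 h). For fructose levels leaving out 1 array tests little, since the other array of that strain and number had nearly the same Cy3 signals. Leaving out both arrays of WT number 1 gave 402 (ΔXlnR), 268 (ΔaraR) and 678 (ΔaraRΔXlnR), and those of WT number 2 gave 459, 383 and 1079. Leaving out both arrays of number 1 or 2 of the deletion strain gave 269 or 290 (ΔXlnR) and 668 or 863 (ΔaraRΔXlnR), while ΔaraR stayed within 1.5 times. The share higher then moved to 19.4% in ΔXlnR and 16.4% in ΔaraR without WT number 1, and to 39.2% and 39.0% in ΔaraR without ΔaraR number 1 and 2.

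Averaging the probes of a gene and scaling between arrays after loess gave identical ratios by construction, since each gene had 1 probe and that scaling leaves ratios unchanged.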

Other observations

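The test of neighbouring genes was chosen after the result was seen, and so were the genes named with it. Neighbours are genes next to each other among the 9081 genes placed in that test, so other genes may lie between them. In ΔXlnR against WT at 8 h the neighbouring genes An08g10860, An08g10870, An08g10880, An08g10930 and An08g10970 had higher responses (4.42, 3.83, 1.95, 3.40 and 1.15). In ΔaraR against WT at 2 h An12g09640, An12g09650, An12g09660 and An12g09670 had lower ones (-4.11, -3.55, -5.75 and -4.83), partly from higher fructose signals (2.07, 1.80, 2.61 and 2.71 in Cy3). In ΔXlnR against WT at 2 h An11g06300, An11g06320 and An11g06330 had lower ones (-5.25, -1.89 and -1.78), and they were lower in ΔaraR at 2 h too (-2.92, -1.71 and -1.84). Neighbours among the 326 genes called in ΔXlnR against WT at 8 h with a change of at least 1 (log2) formed 25 pairs with the same direction, against a mean of 6.56 and a highest of 17 in 1000 random placements. Chance placement of these genes reached that number 0 times (p = 0.000999, the smallest these permutations can give, and adjusted p = 0.00131 over 17 results). Such pairs were not particular to this comparison. The WT response at 2 h had 46, against a mean of 19.38 and a highest of 34 in random placements. The ΔaraRΔXlnR response at 8 h had 3 against a mean of 1.08 (adjusted p = 0.0869 by these permutations). In every other result their adjusted p was 0.00212 or less. Shared control of neighbours may therefore contribute, which was not tested in any other way.

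Among genes with changed fructose levels, An12g02650 was higher in ΔXlnR, ΔaraR and ΔaraRΔXlnR (4.65, 5.22 and 4.43), while An02g08300 was lower (-5.99, -5.72 and -5.15). They were picked after their values were seen.

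Across genes the ratios of partner arrays correlated at r = 0.859 (2 h) and 0.891 (8 h) in WT, 0.923 and 0.899 in ΔXlnR, and 0.568 and 0.620 in ΔaraR. The columns of the value table had medians between -0.131 and 0.110. Arrays sharing a slide had an average correlation of residuals of 0.0630, and arrays of 1 strain and number 0.277.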
